A study of Homo sapiens with 38 samples.

How the data were processed

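Total RNA came from mesenchymal stem or stromal cells of human umbilical cord blood, 1 cell population grown in parallel flasks. Per the series' design text and the labels' protocols, near-confluent cultures were kept in medium with little serum, returned to serum and harvested along a time course, and RNA was isolated on silica columns and labelled as biotinylated cRNA. The samples used here are 21 arrays of the type U133A, at 0 to 8 h in steps of 0.5 h and at 9, 10, 11 and 12 h, and 17 arrays of the type U133B, at 0 to 8 h in steps of 0.5 h. Later sampling times named in the design text were not analysed here. The labels do not say whether the U133A and the U133B array of a time were hybridised with RNA of the same flask.

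The deposited values are linear ratios per probe set, each probe set being set to its own reference by the authors. Per the submitters' processing notes the arrays were summarised with RMA, with no version given. The step from RMA values to ratios is not given in the sources used here, and nor is the reference. From the values themselves, the median ratio of a probe set over the arrays lay within 0.02 of 1 for 78.6% of U133A and 67.0% of U133B probe sets, and under 0.8 for 9.94% and 20.2%. The median ratio of an array was 0.958 to 0.996 on U133A and 0.946 to 0.985 on U133B. A ratio divides out how bright a probe set is, so the array files carry no level against background, and no probe set can be called absent. The number of arrays, not a depth of reads, limits the precision.

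The tests had been laid out for log2 values, and the values turned out to be ratios; log2 of the deposited ratio was used in every test, with no pseudocount. The filter kept genes whose log2 ratio exceeded the median of all values of the array type (a ratio of 0.984 on U133A and 0.963 on U133B, the 0.5 quantile) in at least 2 arrays. Where several probe sets named a gene, the one with the highest mean over all arrays was taken. Because brightness is divided out, neither the filter nor this choice selects by brightness, apart from the probe sets with low ratios on nearly all arrays. The highest mean favours a probe set that rises above its reference, so this choice is not independent of the changes tested. It can enlarge the change given for a gene with several probe sets. With their mean instead, 2344 in place of 2048 U133A genes passed for 5.5 to 8.0 h against 0.5 to 2.0 h, and 124 in place of 73 for 9 to 12 h. The chosen probe set can change when 1 array is left out, and some of the changes given for single genes come from that.

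Probe sets were named from the platform annotation. On U133A, 19071 of 22283 probe sets had 1 gene, 1043 had several and 2169 had none, giving 11963 distinct genes; on U133B, 15432 of 22645 had 1 gene, 554 several and 6659 none, giving 9794. Gene identifiers of 19059 and 15407 probe sets matched the current gene table, which changed 0 symbols. Another 31 and 20 probe sets were never named, by a rule about donor privacy, and 68 control probe sets of each type entered no gene count. After the filter, 11089 U133A and 8623 U133B genes were tested. Control probe sets gave, per array, the mean ratio of 9 spike-in and 12 ribosomal RNA probe sets and the ratio of 5' to 3' probe sets of ACTB and of GAPDH. Sample columns left unused numbered 0.

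Arrays were grouped by time into windows: 0 h (1 array of each type), 0.5 to 2.0 h (4), 2.5 to 5.0 h (6), 5.5 to 8.0 h (6) and, on U133A, 9 to 12 h (4). Each time has 1 array of a type, so there are no true replicates: neighbouring times stand in for them, and the spread within a window holds change over time as well as noise. Windows were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per window, all arrays of a type in 1 fit, two-sided), with Benjamini-Hochberg adjustment over genes at 0.05. The 0 h window is 1 array, assumed to vary like the others. Errors beside a log2 difference are limma standard errors with the moderated spread. Time dependence was the moderated F test of a natural cubic spline of time with 4 degrees of freedom (splines 4.3.3). The 5 h rhythm was the moderated F test of a cosine and a sine term of a 5 h period beside linear and quadratic time. The 5 h period was taken from recall of published work on HES1 in these cells, so the test of HES1 is not independent of that work. For HES1 alone the F statistic was also tested by 100000 permutations of the residuals of the model without the rhythm. Periods of 2 to 8 h were scanned in steps of 0.5 h.

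The 23 gene lists held 476 genes, of which 440 were on either array type: immediate early genes, MAPK feedback inhibitors, secreted and delayed growth factor response, inflammatory NF-kB targets, cholesterol synthesis, quiescence and FOXO targets, G1/S genes, G2/M genes, ribosome biogenesis, circadian clock, somite clock, TGF-beta and BMP targets, SRF and YAP cytoskeletal targets, p53 targets, unfolded protein and amino acid response, heat shock, interferon response, extracellular matrix, and markers of mesenchymal stromal, endothelial, blood and epithelial cells and of adipocytes, muscle and bone. Some genes stand in several lists. Each list with at least 5 tested genes was tested on U133A with limma's camera at a preset correlation of 0.01, adjusted over the 69 tests of 23 lists and 3 window comparisons, and again with the correlation estimated from the data. The estimate reached 0.403, for inflammatory NF-kB targets. For lists with an estimate above 0.01 the preset value makes the p-values much smaller. For the somite clock list the calls were compared with those of other genes by Fisher's exact test, and the median F was ranked among 10000 random lists of the same size matched on mean log2 ratio in 20 bins. A mean log2 ratio holds no expression level.

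Named genes are, for each window comparison, the 10 with the largest rise and the 10 with the largest fall among those past the threshold. For time dependence they are the 10 with the largest fitted range, and for the rhythm the 12 with the largest amplitude, filled up by p where fewer passed. HES1 was always named, and from each list 2 to 4 members with the largest change along and against the list's direction. A few genes outside this rule, such as EGR1 in the window comparisons, CDC6, CDKN1B and INHBA on U133A, were named after their values were seen. Groups, windows, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

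Alternatives were no filter, a filter at the 0.7 quantile, quantile normalization, median centring, no cross-hybridising probe sets, the mean of a gene's probe sets, a trended and robust prior, slopes within windows, a first window of 0.5 to 1.5 h, other spline degrees of freedom, a first-order autoregressive correlation between neighbouring times, other trends, periods and time ranges, other probe sets of a named gene, and leaving out each array in turn. The spike-in ratio as a covariate, the fits without the 0, 2.5 and 3.5 h arrays and the 2 other scalings for the gene lists were chosen after seeing the data. Comparisons of windows with at least 3 arrays on each side were repeated on 100 splits of their arrays.

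The tests were also run on simulated data with independent normal noise of each gene's residual spread, 100 genes being changed at each size. For the 3 U133A window comparisons on 11089 genes, in order of time, 84%, 98% and 96% of genes changed by 1 on the log2 scale were recovered; for the 2 U133B comparisons on 8623 genes, 83% and 97%. The rhythm test recovered 69% of genes with an amplitude of 0.3 on each type and 99% (U133A) and 98% (U133B) at 0.6. Time dependence recovered 90% and 88% of genes with a range of 1. False calls made up 2.33% to 7.07% of the calls. Of 2 shifted lists 2 were recovered, with 0 calls in 67 other tests, and the HES1 test gave p under 0.05 in 6% of 200 runs without a rhythm and 100% of 50 runs with one. The simulated noise was independent between genes and between times. These runs thus do not show how often lists of correlated genes are called falsely. The HES1 runs without a rhythm held no early pulse, so they do not show how the test treats one. Figures and tables used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.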

Results

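Mesenchymal stem or stromal cells of human umbilical cord blood were followed after serum was returned to cultures held for a day in medium with little serum, on 21 U133A arrays from 0 to 12 h and 17 U133B arrays from 0 to 8 h. In the first 2 h genes of the immediate early response, feedback inhibitors of MAPK signalling and inflammatory NF-kB targets were higher than on the single 0 h array, led by NR4A2, CXCL8 and PTGS2. Between 5.5 and 8.0 h most immediate early genes had fallen again, while genes of the secreted and delayed growth factor response, such as MMP3 and HAS2, and genes of ribosome biogenesis had risen. By 9 to 12 h genes of the G1/S step, such as MCM5 and CCNE2, were higher. HES1, a cyclic gene of the somite clock, had its highest values at 0.5 to 1.5 h. Each time had 1 array of a type, so there were no true replicates, and the p-values measure only the spread between neighbouring times of this 1 culture series, which may be technical.

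The 0 h array stood apart in its ribosomal RNA and ACTB controls on both types. Its spike-in probe sets had a mean ratio of 1.46 on U133A, above the 0.591 to 1.39 of the other arrays, and of 1.19 on U133B, within their 0.729 to 1.26. The ribosomal RNA probe sets stood at 1.56 and 1.57, against 0.620 to 1.39 and 0.676 to 1.27, and the 5' to 3' ratio of ACTB at 0.837 and 0.776, against 0.890 to 1.15 and 0.886 to 1.15. The 5' to 3' ratio of GAPDH did not stand apart, at 1.04 and 0.992, within the 0.838 to 1.10 and 0.831 to 1.14 of the other arrays. Every comparison with 0 h rests on this 1 array of each type, assumed to vary like the others, and its p-values cannot tell an effect of serum from what set this array apart.

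In the first 2 h after serum, the orphan nuclear receptors NR4A2 (25.4-fold, log2 4.67 ± 0.61), NR4A3 (11.5-fold, 3.52 ± 0.59) and NR4A1 (9.95-fold, 3.31 ± 0.41) rose on U133A. The other largest rises were those of the chemokines CXCL8 (23.5-fold, 4.56 ± 0.71) and CXCL2 (3.32 ± 0.54), the prostaglandin synthase PTGS2 (13.4-fold, 3.75 ± 0.59) and the transcription factor EGR3 (13.1-fold, 3.71 ± 0.59). Among the 10 were also the cytokines IL6 (12.5-fold, 3.64 ± 0.36) and LIF (10.1-fold, 3.33 ± 0.37), and the NF-kB inhibitor TNFAIP3 (10.4-fold, 3.38 ± 0.39). The thioredoxin-binding protein TXNIP fell 5.93-fold (log2 −2.57 ± 0.57), the peptide hormone ADM 3.41-fold (−1.77 ± 0.36), the AP-1 subunit JUN 3.22-fold (−1.69 ± 0.26) and the mTORC1 inhibitor DDIT4 3.08-fold (−1.62 ± 0.33). TMT1A (−1.37 ± 0.25), APP (−1.20 ± 0.28), OARD1 (−1.18 ± 0.25), DEPP1 (−1.16 ± 0.20), TIA1 (−1.13 ± 0.20) and the proteoglycan LUM (−1.12 ± 0.27) also fell. FOS, already high at 0 h, was not called (−3.15 ± 1.02, adjusted p = 0.187), and nor were EGR1 (−0.25 ± 0.62, adjusted p = 0.927) and HES1 (1.47 ± 0.48, adjusted p = 0.186). In all, 92 of 11089 genes passed (limma, 4 arrays against 1), 55 higher and 37 lower, of which 49 and 12 changed at least 2-fold, and 1360 had an unadjusted p under 0.05.

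Most of the falls and part of the inflammatory rises were lost with quantile normalization, but not with median centring, which gave 92 genes (58 higher, 34 lower) and ended 0 of the 20 named calls. With quantile normalization 26 genes passed, 24 higher and 2 lower in place of 55 and 37, and the calls of CXCL8 (log2 1.77), PTGS2 (1.49), EGR3 (2.15) and CXCL2 (2.06) were lost. So were those of TXNIP (−1.48), DDIT4 (−0.96), TMT1A (−0.23), APP (−0.80), OARD1 (−0.81), DEPP1 (−0.80), TIA1 (−0.72) and LUM (−0.72). Quantile normalization gives every array the same distribution of values. Before it, the SD of the centred log2 ratios over genes ran from 0.172 at 4.5 h to 0.350 at 0 h. Calls lost against 0 h or gained in later windows can follow from this alone, which was not tested. With slopes within windows 173 genes passed, and between 63 (without 1 h) and 179 (without 0.5 h) when 1 array was left out. APP lost its call in 9 of 20 such runs, LUM in 10, TMT1A in 9, OARD1 in 2 and TXNIP in 1, while the other 15 named genes kept theirs. A first window of 0.5 to 1.5 h ended the calls of EGR3 (3.69), DDIT4 (−1.39), APP (−1.21) and LUM (−1.02). The mean of the probe sets ended those of APP (−0.93) and TIA1 (−0.63), and a trended robust prior those of TXNIP, DDIT4 and LUM, and slopes within windows that of LUM. The spike-in covariate, chosen after seeing the data, ended that of LUM too (−1.20). Another probe set gave 0.14 for NR4A1 and −0.11 for NR4A3, although a further one of each kept the call. Leaving out cross-hybridising probe sets ended the call of NR4A1 (0.14), whose chosen probe set is of that kind. The falls of TMT1A, APP and TIA1 were each called on 1 probe set alone, the others giving −0.38 and −0.18, −0.75 and −0.85, and −0.35 to −0.80, not called.

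Immediate early genes rose as a list in the first 2 h (median log2 difference 1.32), with NR4A2, PTGS2 and EGR3 in front and JUN going against it. The p-values given for lists against 0 h rest on the 1 array at 0 h and on the preset correlation. For the lists that rose they were much larger with an estimated correlation. Of 31 tested, 15 were higher and 1 lower over all genes, and 20 and 2 adjusted over the list alone. Inflammatory NF-kB targets rose with CXCL8, IL6 and TNFAIP3 (adjusted p = 1.95e-25), while IL1B stood at −0.06. Of these 20 genes, 6 were higher and 0 lower over all genes, and 15 and 0 adjusted over the list alone. MAPK feedback inhibitors rose (adjusted p = 8.02e-12), among them the phosphatases DUSP5 (log2 3.10 ± 0.23) and DUSP1 (1.74 ± 0.35). The receptor-signalling inhibitor SPRY2 rose too (1.94 ± 0.23, but 0.84 and not called with quantile normalization), and DUSP10 stood at −0.62 ± 0.28 and was not called. Of the 13 genes, 6 were higher and 0 lower over all genes, and 8 and 1 adjusted over the list alone.

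TGF-beta and BMP targets rose in the first 2 h with the helix-loop-helix inhibitors ID1 (log2 3.27 ± 0.32) and ID3 (3.19 ± 0.51) and with SMAD7 (2.41 ± 0.40), and BMP4 stood at −0.66 ± 0.20, not called (adjusted p = 4.86e-09). Of 17 tested, 5 were higher and 0 lower over all genes, and 6 and 1 adjusted over the list alone. Somite clock genes rose with ID1, SPRY2 and ID2 (1.76 ± 0.32), CCND1 standing at −0.35 (adjusted p = 7.29e-07). Here 4 of 26 were higher and 0 lower over all genes, and 6 and 0 adjusted over the list alone. SRF and YAP cytoskeletal targets rose (adjusted p = 2.35e-09), with the actin-binding protein CNN1 (1.01 ± 0.19) as the only one of 17 called over all genes, and 8 higher and 0 lower adjusted over the list alone. Of the others, ZYX stood at 1.62 ± 0.60, THBS1 at 1.23 ± 0.39 and ACTA2 at −0.27. Secreted and delayed growth factor genes rose with LIF and the EGF receptor ligand EREG (1.63 ± 0.33, but 0.69 and not called with quantile normalization), MMP1 standing at −0.63. Their adjusted p = 6.55e-05 became adjusted p = 0.122 with an estimated correlation. Of the 18 genes, 2 were higher and 0 lower over all genes, and 3 and 0 adjusted over the list alone.

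Cell-cycle genes were lower as groups in the first 2 h, with CCNB1 (log2 −0.82 ± 0.22) and BIRC5 (−0.61) among G2/M genes and UNG (−0.77 ± 0.21) and RRM1 (−0.70) among G1/S genes, none of these 4 called. G2/M genes had an adjusted p = 0.000122, but adjusted p = 0.261 with an estimated correlation. Of 25, 0 passed over all genes, and 0 were higher and 2 lower adjusted over the list alone. G1/S genes had an adjusted p = 0.0189, but adjusted p = 0.477 with an estimated correlation, with 0 of 24 passing over all genes, and 0 higher and 3 lower adjusted over the list alone. Quiescence and FOXO targets did not pass as a group (adjusted p = 0.105, but 0.0267 without the 0.5 h array and 0.0127 with slopes within windows). TXNIP was the only one of 20 called over all genes, 0 were higher and 4 lower adjusted over the list alone, and the cyclin-dependent kinase inhibitor CDKN1B stood at −1.88 ± 0.48 (adjusted p = 0.07). Ribosome biogenesis (20 tested, adjusted p = 0.296) and cholesterol synthesis (17 tested, adjusted p = 0.840) had 0 members called, over all genes and adjusted over the list alone.

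**Figure D1:**
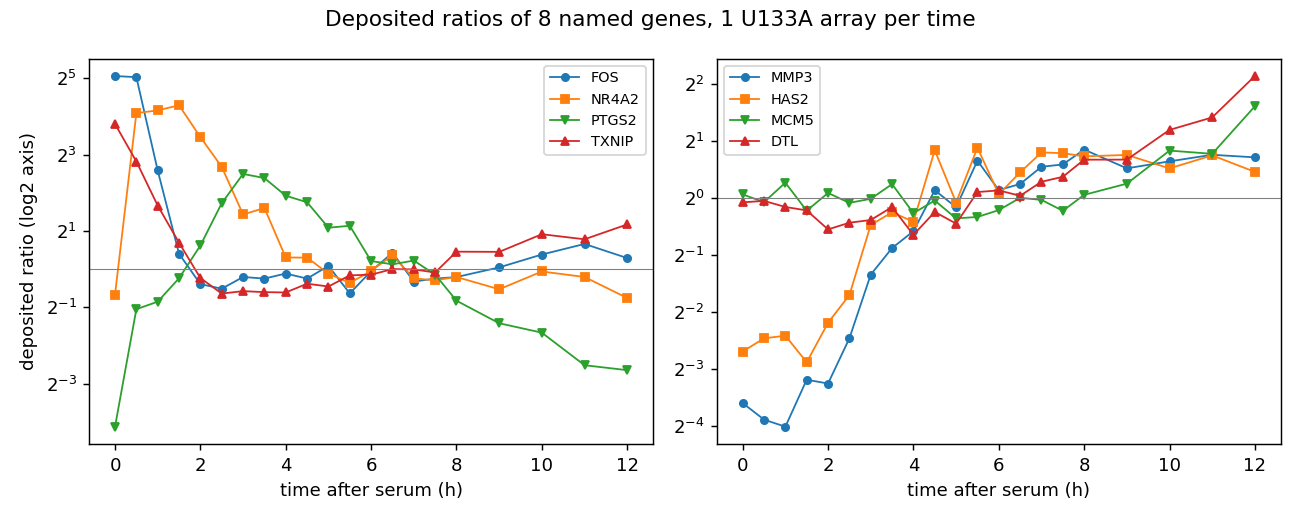
Deposited ratio (log2 axis) of FOS, NR4A2, PTGS2 and TXNIP (left) and of MMP3, HAS2, MCM5 and DTL (right) against hours after serum, 1 U133A array per time.

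Between 0.5 to 2.0 h and 5.5 to 8.0 h the metalloproteinase MMP3 rose 17.1-fold (log2 4.09 ± 0.32), the cytokine IL33 10.3-fold (3.36 ± 0.39), the hyaluronan synthase HAS2 8.62-fold (3.11 ± 0.28) and the purine enzyme PNP 6.49-fold (2.70 ± 0.16). G0S2 (2.60 ± 0.25), the secreted glycoprotein STC1 (2.49 ± 0.19), NAV3 (2.37 ± 0.19), the cytokine receptor IL7R (2.31 ± 0.23), ANXA10 (2.26 ± 0.29) and the phospholipase PLA2G4A (2.23 ± 0.21) followed. The transcription factors ATF3 (19.4-fold, −4.28 ± 0.36), NR4A2 (17.5-fold, −4.13 ± 0.35), EGR3 (14.3-fold, −3.84 ± 0.34), NR4A1 (−3.43 ± 0.24), FOSB (−3.15 ± 0.30), NR4A3 (−3.13 ± 0.34), and CEBPD (−2.51 ± 0.30) fell most. With them fell REL (−2.50 ± 0.42), EGR4 (−2.44 ± 0.29) and the chemokine CXCL2 (−2.83 ± 0.31). FOS fell as well (−2.08 ± 0.59, adjusted p = 0.0141), and so did HES1 (−0.99 ± 0.27, adjusted p = 0.0121), whereas EGR1 stood at −0.95 ± 0.36 (adjusted p = 0.0689). In limma 2048 genes passed (6 arrays against 4), 1196 higher and 852 lower, 97 and 100 of them at least 2-fold, and 3195 at an unadjusted p under 0.05.

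All 20 named genes kept their calls whichever array was left out, when 1624 (without 1 h) to 2126 genes passed. Quantile normalization gave 947 higher and 763 lower, and median centring 1010 higher and 1057 lower. Probe sets of some genes disagreed. Those of NAV3 other than the one taken gave 0.07 and 0.01. For REL another gave −0.11, but its U133B probe set gave −3.00. Others gave −0.62 for EGR4, −0.23 for NR4A1 (adjusted p = 0.136) and 0.10 for NR4A3, although a further probe set of each kept the call, and −0.67 (adjusted p = 0.0480) and −0.04 for HES1. Leaving out cross-hybridising probe sets ended the call of NR4A1 here as well (−0.23, adjusted p = 0.134). EGR4 stood at −0.54, still called, with quantile normalization. HES1 lost its call with quantile normalization (−0.47) and without the 0.5, 1 or 1.5 h array (−0.07, −0.03 and −0.06), when the last of these was taken.

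Immediate early genes fell between the first window and 5.5 to 8.0 h (adjusted p = 1.31e-21), with ATF3, NR4A2 and EGR3 in front and PTGS2 (0.50) and JUN (0.42) not called. Of 31 tested, 0 were higher and 22 lower over all genes, and 1 and 23 adjusted over the list alone. Secreted and delayed growth factor genes rose (adjusted p = 4.19e-11), with MMP3, HAS2, STC1 and the collagenase MMP1 (2.03 ± 0.19), against LIF (−0.91 ± 0.21). Of these 18, 13 were higher and 1 lower over all genes, and 14 and 2 adjusted over the list alone. Ribosome biogenesis rose (adjusted p = 2.81e-07), with the assembly factors MRTO4 (0.89 ± 0.14) and RRS1 (0.84 ± 0.13) and the helicase DDX21 (0.76 ± 0.14), while POLR1B stood at −0.12. Here 14 of 20 were higher and 0 lower over all genes, and 15 and 0 adjusted over the list alone. Quiescence and FOXO targets fell (adjusted p = 6.72e-08), with the insulin receptor substrate IRS2 (−1.70 ± 0.23), TXNIP (−1.23 ± 0.33, but −0.70 and not called without 0.5 h) and the repressor BCL6 (−1.03 ± 0.14), against CITED2 at 0.28, not called. Of the 20 genes, 0 were higher and 11 lower over all genes, and 0 and 12 adjusted over the list alone. With an estimated correlation these lists had an adjusted p of 0.00409, 0.0134, 0.0251 and 0.0310, in the order given.

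Inflammatory NF-kB targets split by 5.5 to 8.0 h: CXCL2, REL and CXCL3 (−1.96 ± 0.37) fell, CCL7 (1.54 ± 0.17) and CXCL6 (1.19 ± 0.20) rose, and CXCL8 stood at 1.15 ± 0.41 (adjusted p = 0.0528). The list of 20 fell, with 4 higher and 7 lower over all genes, and 5 and 7 adjusted over the list alone. Its adjusted p = 0.0215 became adjusted p = 0.546 with an estimated correlation, 0.0800 without 1.5 h and 0.367 without 2.0 h, and, in scalings chosen after seeing the data, 0.105 with quantile normalization and 0.0589 with median centring. TGF-beta and BMP targets fell with TGIF1 (−1.19 ± 0.18), ID1 (−1.09 ± 0.19) and ID3 (−1.03 ± 0.29), against LTBP2 at 0.37, not called. Of 17, 0 were higher and 5 lower over all genes, and 1 and 6 adjusted over the list alone. Their adjusted p = 0.0366 became adjusted p = 0.398 with an estimated correlation, 0.0762 without 1.5 h, 0.206 without 2.0 h and 0.0524 without 8 h, and 0.0873 and 0.0591 with the same 2 scalings.

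G2/M genes fell between the first window and 5.5 to 8.0 h with the spindle proteins TPX2 (−0.72 ± 0.16) and KIF20A (−0.52 ± 0.13), against AURKA at 0.23, not called. Of 25, 0 were higher and 5 lower over all genes, and 0 and 6 adjusted over the list alone. The adjusted p = 0.0210 became adjusted p = 0.5004 with an estimated correlation, 0.0782 without 0.5 h and 0.0579 without 6 h. Cholesterol synthesis rose with the enzymes MSMO1 (1.19 ± 0.21) and SQLE (0.73 ± 0.16) and the sterol sensor INSIG1 (1.00 ± 0.20), against LSS at −0.30, not called. Of 17, 3 were higher and 0 lower over all genes, and 5 and 0 adjusted over the list alone. The adjusted p = 0.0447 became adjusted p = 0.425 with an estimated correlation, and the call was lost in 8 of the runs without 1 array, with adjusted p up to 0.122 without 8 h.

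MAPK feedback inhibitors were divided between 5.5 to 8.0 h and the first window: the phosphatase DUSP6 (1.65 ± 0.25) and SPRY2 (0.95 ± 0.13) rose, and DUSP5 (−1.83 ± 0.13) and DUSP1 (−1.61 ± 0.20) fell. Of 13, 3 were higher and 4 lower over all genes and adjusted over the list alone (adjusted p = 0.200). Somite clock genes were divided as well, with HAS2 and DUSP6 higher and ID1 and HES1 lower (adjusted p = 0.849). Of 26, 6 were higher and 4 lower over all genes, and 6 and 7 adjusted over the list alone. G1/S genes did not pass as a group (adjusted p = 0.498), although the cyclin CCND1 (0.58 ± 0.09) and the nuclease FEN1 (0.54 ± 0.12) rose, with PCNA at −0.46, not called. Of 24, 3 were higher and 0 lower over all genes and adjusted over the list alone. SRF and YAP cytoskeletal targets did not pass (adjusted p = 0.498), with 2 of 17 higher and 2 lower over all genes, and 4 and 2 adjusted over the list alone. The actin ACTG2 rose (0.77 ± 0.08), and the fall of CALD1 (−0.62 ± 0.17) was lost with quantile normalization (−0.24) and turned to 0.07 as the mean of its probe sets.

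**Figure D2:**
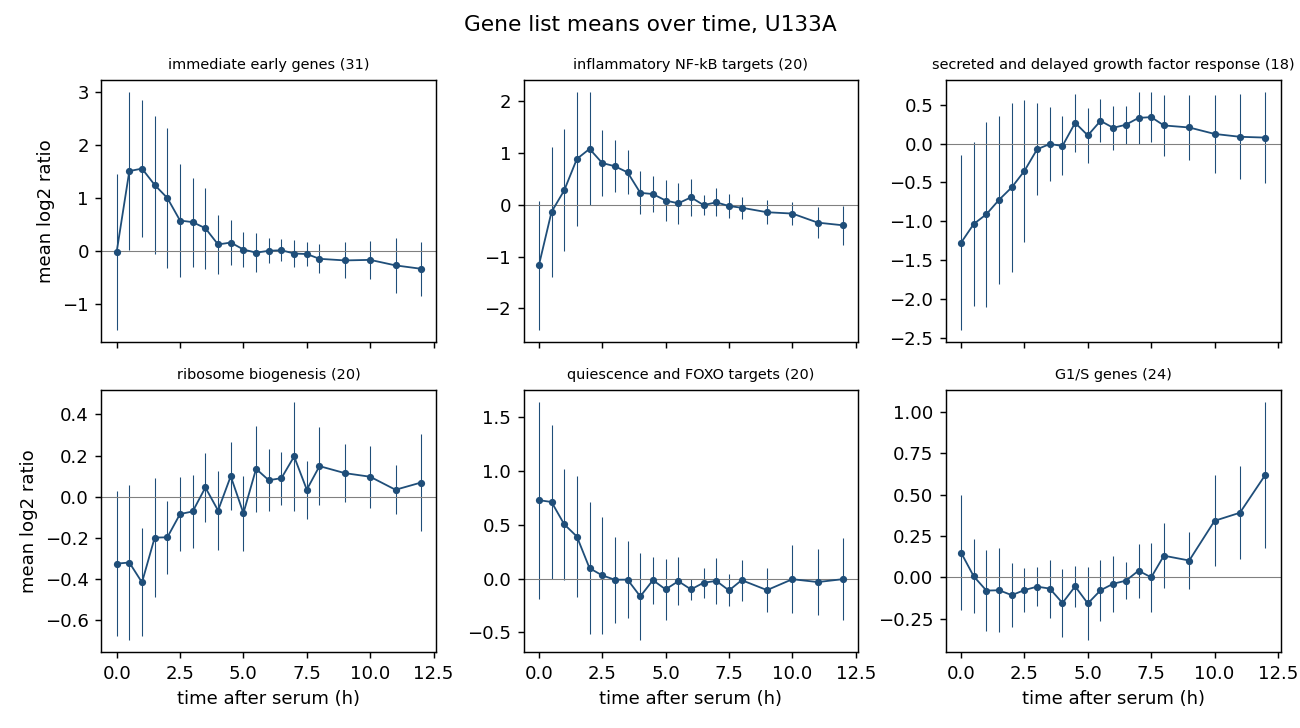
Mean log2 ratio over the members of 6 gene lists (± SD over members, not over arrays) against hours after serum, 1 U133A array per time. The number of members is 31, 20, 18, 20, 20 and 24 in the order of the panels.

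From 5.5 to 8.0 h on to 9 to 12 h, on U133A the transcription factor MYBL1 rose 2.68-fold (log2 1.42 ± 0.23), the chromatin protein HMGB2 2.29-fold (1.20 ± 0.26) and LRRN3 2.28-fold (1.19 ± 0.15). The replication regulators DTL (2.13-fold, 1.09 ± 0.18) and GMNN (0.88 ± 0.19), the replicative helicase subunit MCM5 (1.99-fold, 0.99 ± 0.17) and the kinetochore protein ZWINT (0.87 ± 0.16) rose as well, and so did CSTF3 (0.84 ± 0.16), the cyclin CCNE2 (0.82 ± 0.15) and the neurofilament NEFM (0.73 ± 0.13). PTGS2 fell 4.54-fold (−2.18 ± 0.34), the alcohol dehydrogenase ADH1B 2.43-fold (−1.28 ± 0.20), the growth factor BMP2 2.23-fold (−1.16 ± 0.18) and TMT1A 2.13-fold (−1.09 ± 0.14). RGCC (−0.85 ± 0.18), the potassium channel KCNJ15 (−0.84 ± 0.13), CSGALNACT1 (−0.80 ± 0.14), the adenosine receptor ADORA2B (−0.78 ± 0.15), ANGPTL4 (−0.77 ± 0.16) and NINJ1 (−0.75 ± 0.16) fell too. HES1 was not called, with a mean log2 ratio of 0.11 and then 0.04. In limma 73 genes passed (4 arrays against 6), 28 higher and 45 lower, 4 and 4 of them at least 2-fold, and 1127 at an unadjusted p under 0.05.

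This later count depended on the setting: 185 genes passed with quantile normalization (84 higher, 101 lower), 199 with slopes within windows, 124 with the mean of the probe sets and 88 with median centring. Without 1 array it was 25 without 12 h, 26 without 11 h, 39 without 10 h, 44 without 6.5 h, 111 without 8 h and 116 without 2.0 h, and lay between 56 and 106 in the other runs. MYBL1, LRRN3, DTL, MCM5, CCNE2, NEFM, PTGS2, BMP2, KCNJ15, CSGALNACT1 and ADORA2B kept their calls in all 21 such runs. TMT1A lost its call in 10 runs and changed sign to 0.07, and ADH1B in 4, to 0.07 without 0, 0.5 or 1 h, because other probe sets were taken. HMGB2 lost its call in 6 runs, GMNN and NINJ1 in 5 each, ANGPTL4 and RGCC in 3 each, and CSTF3 and ZWINT in 1 each. Quantile normalization ended the calls of ADH1B (−0.71) and TMT1A (0.09). Other probe sets gave 0.83 for LRRN3, 0.26 for MCM5, −0.26 for KCNJ15 and −0.73 and 0.07 for ADH1B, none called.

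The ribosomal RNA control moved with the last window, its ratio being 1.223 to 1.385 on the 4 arrays of 9 to 12 h, above the 0.760 to 1.219 of the 6 arrays of 5.5 to 8.0 h, and the spike-in ratio was 1.10 to 1.19 against 0.815 to 1.39. G1/S genes rose as a group between these windows (adjusted p = 1.74e-19), with MCM5, CCNE2 and MCM2 (log2 0.69 ± 0.11) called and the replication licensing factor CDC6 at 0.63 (adjusted p = 0.0512). Of 24, 4 were higher and 0 lower over all genes, and 15 and 0 adjusted over the list alone. G2/M genes rose (adjusted p = 2.03e-10) with the mitotic activator CDC20 (0.53 ± 0.12), whose own call was lost in 7 runs without 1 array. Of 25, 1 was higher and 0 lower over all genes, and 2 and 0 adjusted over the list alone. Cholesterol synthesis rose (adjusted p = 6.17e-07), with MVK called (0.41 ± 0.09, lost in 8 runs) and MSMO1 (0.66 ± 0.21) and HMGCS1 (0.64 ± 0.21) not called. Of 17, 1 was higher and 0 lower over all genes, and 9 and 0 adjusted over the list alone. With an estimated correlation the G1/S, G2/M and cholesterol lists had an adjusted p of 0.00973, 0.0467 and 0.0303.

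MAPK feedback inhibitors fell between the last 2 windows (adjusted p = 0.000536) with DUSP5 (−0.66 ± 0.13, lost without 11 or 12 h), while SPRY4 at −0.76 and DUSP10 at 0.37 were not called. Of 13, 0 were higher and 1 lower over all genes, and 0 and 5 adjusted over the list alone. With an estimated correlation this list had an adjusted p = 0.0303. NF-kB targets fell as a group only, CXCL8 standing at −0.84 ± 0.41 and RELB at −0.66, with 0 of 20 called over all genes and adjusted over the list alone. Their adjusted p = 0.000188 became adjusted p = 0.383 with an estimated correlation. Immediate early genes fell with PTGS2 and the kinase SGK1 (−0.75 ± 0.14, lost without 11 or 12 h), FOS standing at 0.52, and 0 of 31 were higher and 2 lower over all genes and adjusted over the list alone. Their adjusted p = 0.00329 became adjusted p = 0.367 with an estimated correlation.

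Secreted and delayed growth factor genes did not pass between the last 2 windows (adjusted p = 0.0705, but 0.00472 with slopes within windows and 0.00501 with the mean of the probe sets). BMP2 was the only one of 18 called over all genes, and 1 was higher and 4 lower adjusted over the list alone. Somite clock genes did not pass (adjusted p = 0.0642, but 0.0226 with slopes within windows), with 0 of 26 called over all genes, and 0 higher and 2 lower adjusted over the list alone. SRF and YAP targets (17 tested, adjusted p = 0.0737, but 0.0420 without 5.5 h), quiescence and FOXO targets (20 tested, adjusted p = 0.817), ribosome biogenesis (adjusted p = 0.541) and TGF-beta and BMP targets (adjusted p = 0.278) had 0 members called, over all genes and adjusted over the list alone. TXNIP stood at 0.82, not called. Over the 3 comparisons, 30 of 69 list tests passed, 16 of them also with an estimated correlation. Between 19 and 33 passed without 1 array, the fewest without 0 h, when 1 comparison could not be made.

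On U133B, which carries mostly other genes, the largest early rises were those of C11orf96 (5.89-fold, log2 2.56 ± 0.49) and of the EGF receptor inhibitor ERRFI1 (4.73-fold, 2.24 ± 0.25), then CSRNP1 (1.85 ± 0.26), the activin subunit INHBA (1.79 ± 0.29), SERTAD1 (1.70 ± 0.32), ZNF281 (1.65 ± 0.28) and SNX8 (1.07 ± 0.14). The collagen COL3A1 (−1.33 ± 0.26), DST (−1.31 ± 0.25), SLC25A36 (−1.09 ± 0.20) and ANXA1 (−1.05 ± 0.20) fell. These 11 genes, 7 higher and 4 lower, were all that passed of 8623 (limma, 4 arrays against 1; 596 at an unadjusted p under 0.05). The U133A probe set of INHBA did not move (−0.09 ± 0.19), and another probe set gave −0.19 for SLC25A36 and 1.59 for ZNF281, not called. Quantile normalization left 4 genes (4 higher, 0 lower), a first window of 0.5 to 1.5 h 5, and slopes within windows gave 43. With the spike-in ratio as a covariate, chosen after seeing the data, 7 passed. Without 1 array 37 passed without 0.5 h, 4 without 1 h, 5 without 4.5 h, 6 without 1.5, 3, 4 or 8 h and 7 without 7.5 h. Only ERRFI1, CSRNP1, INHBA and SNX8 kept their calls in all 16 such runs, and COL3A1 lost its call in 13, C11orf96, DST and SERTAD1 in 7 each, ANXA1 in 6, SLC25A36 in 5 and ZNF281 in 2. The first window of 0.5 to 1.5 h ended 7 of the 11 calls, among them those of CSRNP1 (1.91) and INHBA (1.62), and quantile normalization 7, among them that of INHBA (1.13). A trended robust prior ended those of CSRNP1 (adjusted p = 0.0739) and SLC25A36, and the stricter filter and the removal of cross-hybridising probe sets that of COL3A1.

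By 5.5 to 8.0 h HAS2 (7.54-fold, log2 2.91 ± 0.22), IL7R (7.30-fold, 2.87 ± 0.23) and the collagen-binding integrin ITGA2 (2.12 ± 0.20) had risen on U133B against the first window, and so had CAVIN4 (1.80 ± 0.21). They were followed by the TNF family ligand TNFSF15 (1.79 ± 0.18), NRXN3 (1.65 ± 0.19), the Argonaute protein AGO2 (1.61 ± 0.35), the amino acid transporter SLC7A2 (1.55 ± 0.15), PWWP3B (1.39 ± 0.19) and the keratin-associated KRTAP4-12 (1.37 ± 0.18). The NF-kB subunit REL fell 7.97-fold (−3.00 ± 0.54) and DACH1 4.87-fold (−2.28 ± 0.29), followed by ARHGAP28 (−2.25 ± 0.25), the NF-kB regulator NFKBIZ (−2.23 ± 0.40), JMY (−2.21 ± 0.28), the AP-1 subunit FOSL2 (−1.99 ± 0.33), SIPA1L2 (−1.98 ± 0.19), PXK (−1.90 ± 0.31), SCAI (−1.84 ± 0.20) and CREBRF (−1.83 ± 0.19). In limma 804 genes passed (6 arrays against 4), 419 higher and 385 lower, 35 and 71 at least 2-fold, and 1823 at an unadjusted p under 0.05. Without 1 array 582 to 857 passed, and 19 of the 20 named genes kept their calls. SLC7A2 changed sign (to −0.29) without 5.5, 6, 6.5, 7 or 7.5 h, because its other probe set (−0.26) was taken. Another probe set of PXK gave −0.11.

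Of the genes that both array types carried, 3483 were tested on each for 5.5 to 8.0 h against the first window. The changes of HAS2, IL7R and REL had the same sign and similar size on both. Across these genes the 2 types' log2 differences correlated with r = 0.547, where genes are not independent replicates. Of 745 genes called on U133A, 579 had the same sign on U133B, and 200 were called on both, 196 of them with the same sign, where 77.6 would be called on both if the calls were independent. The 168 probe sets on both types, 68 of them controls, had a median Pearson r of 0.549 and Spearman of 0.529 over 17 times, against 0.0446 for mismatched probe sets, and 98 exceeded 0.5.

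Over the whole course, FOS had the largest fitted range on U133A (log2 6.16, 71.6-fold, highest at 0 h). It was followed by CXCL8 (5.74, highest at 3 h), PTGS2 (5.64, 3.5 h), MMP3 (4.89, 12 h), TXNIP (4.59, 0 h), G0S2 (4.31, 6.5 h), NR4A2 (4.14, 2 h), NR4A3 (4.01, 2.5 h), IL33 (3.94, 12 h) and EGR3 (3.87, 2 h). The range of CXCL8 was 3.22 without the 0 h array and 3.25 with quantile normalization. On U133B they were REL (3.94, highest at 2 h), HAS2 (3.71, 8 h), IL7R (3.60, 8 h), the zinc finger protein HIVEP3 (3.52, 3 h), C11orf96 (3.01, 2.5 h) and LURAP1L (2.996, 0 h). The ubiquitin ligase MYLIP (2.91, 0 h, but not called without 0 or 0.5 h), CAVIN4 (2.91, 4.5 h), INHBA (2.88, 4 h) and RUNX1T1 (2.85, 0 h) completed the 10. With limma's spline test 3289 of 11089 U133A genes (29.7%) depended on time, and 785 had a fitted range of at least 1 log2 unit. Of the 3289, 1422 were highest between 0 and 2 h, 600 between 2.5 and 5 h, 376 between 5.5 and 8 h and 891 later. On U133B 1024 of 8623 (11.9%) did, 525, 152 and 347 in the first 3 of these spans, 381 with such a range. With a correlation between neighbouring times the counts were 5487 and 2860 (the estimates were −0.39 and −0.36). These estimates, and those used for the rhythm, were not corrected for the fit. Fitting alone makes neighbouring residuals negatively correlated, so the estimates may be too negative. Without 1 array the counts ran from 2754 to 3453 and from 776 to 1108. Without the 0, 2.5 and 3.5 h arrays, a setting chosen after seeing the data, 664 U133B genes passed.

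HES1 went after serum from a ratio of 0.774 at 0 h to 2.59, 3.74 and 2.87 at 0.5, 1 and 1.5 h, was back at 0.763 at 2 h, dipped to 0.527 at 2.5 h and reached 1.25 at 5.5 h. Its geometric mean ratio was 2.15 in the first window, then 0.701, 1.08 and 1.02 in the later 3. A 5 h wave had an amplitude of log2 0.63 ± 0.16 with a first peak at 0.94 h, and the HES1 test alone gave a permutation p = 0.0201 (F = 4.97, 21 arrays), whereas limma over all genes gave an adjusted p = 0.653. The amplitude was 0.67 with a linear trend (permutation p = 0.00656), 0.61 with a cubic trend (p = 0.0277), 0.72 up to 8 h (p = 0.0254) and only 0.26 from 2.0 h on (p = 0.00652), after the first peak. It was 0.56 for a period of 4 h (permutation p = 0.0427), 0.43 for 3 h (p = 0.166), 0.52 for 6 h (p = 0.0674) and 0.45 for 7 h (p = 0.115). Without 1 array it ran from 0.54 to 0.71, with permutation p up to 0.0486. Other HES1 probe sets had amplitudes of 0.45 (permutation p = 0.0454) and 0.09 (p = 0.0319). The permutations take the times as exchangeable, so 1 early pulse, or the later dip and return alone, can also give a small p. None of these p-values can therefore tell a 5 h rhythm from another smooth change after serum.

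**Figure D3:**
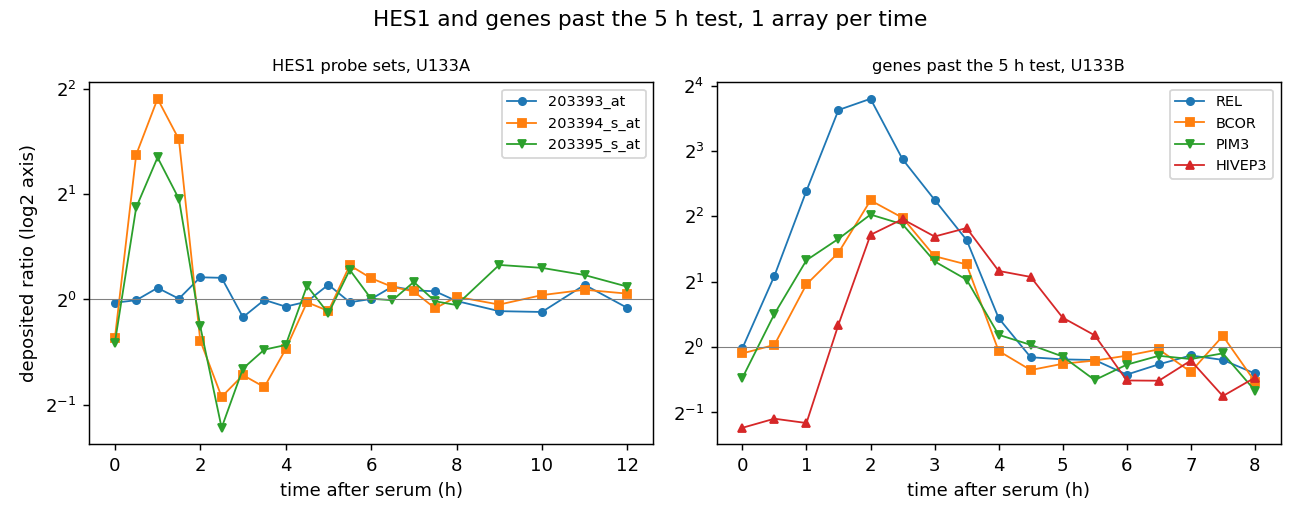
Left, deposited ratio (log2 axis) of 3 HES1 probe sets on U133A; right, the same for REL, BCOR, PIM3 and HIVEP3 on U133B, the 4 genes with the largest 5 h amplitude there. There was 1 array per time and type.

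On U133B, 74 of 8623 genes passed the test for a 5 h rhythm (limma; 624 at an unadjusted p under 0.05), 64 of them with the first peak between 1.5 and 3 h and a median of 2.31 h. The largest amplitudes were those of REL (log2 1.40 ± 0.15), the BCL6 corepressor BCOR (0.94 ± 0.09), the kinase PIM3 (0.87 ± 0.08), HIVEP3 (0.85 ± 0.11) and IER5L (0.73). Then came the SMAD corepressor SKIL (0.73), FOSL2 (0.73), the Notch coactivator MAML3 (0.71), DIDO1 (0.64), SPIDR (0.59), DLC1 (0.54) and SERTAD1 (0.53). None of the 12 passed with the arrays from 2.0 h on, where 0 genes passed (limma; 855 unadjusted), or with periods of 3 or 4 h (0 and 0 genes). A linear trend ended 5 of the 12 calls (12 genes passing) and a cubic trend 2 (35 genes passing). Periods from 4.5 to 8 h each gave 50 to 79 genes, so the period was not resolved. Without 1 array 31 (without 0 h), 38 (without 2.0 h and without 2.5 h) or up to 79 genes passed, with a correlation between neighbouring times 450, and without the 0, 2.5 and 3.5 h arrays, a setting chosen after seeing the data, 16. SPIDR lost its call without 0 h, SERTAD1 without 0, 1.5, 2.0, 2.5 or 4 h, and DIDO1 dropped to an amplitude of 0.07 without 2.0 h and 0.08 without 2.5 h. The mean of the probe sets also ended the call of SPIDR (amplitude 0.30, limma adjusted p = 0.144).

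On U133A 0 of 11089 genes passed for a 5 h rhythm (limma, smallest adjusted p = 0.299; 562 at an unadjusted p under 0.05). With the arrays up to 8 h 83 passed, with a correlation between neighbouring times 53, with quantile normalization 1 (KDM3A), and for a period of 7 h 69. Periods of 7.5 and 8 h gave 160 and 239, 6.5 h gave 7 and the other periods 0. The 12 genes with the smallest p, none of them passing, were the histone demethylase KDM3A (amplitude log2 0.49), the ephrin receptor EPHA2 (0.39), the Wnt effector TCF7L2 (0.29), the thiamine transporter SLC19A2 (0.56), FHOD3 (0.52), MTCL1 (0.32) and ZBTB1 (0.37), and also the transcription factors GATA6 (0.51), HIVEP1 (0.66) and SNAI2 (0.51), the kinase NUAK1 (0.35) and IRS2 (0.39). Each of these 12 passed either up to 8 h or with the correlation between neighbouring times.

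Known somite clock genes ranked high in the test for 5 h waves on U133A among genes of similar mean log2 ratio. On U133A 26 of 39 were tested and 0 passed over all genes (limma), 8 had an unadjusted p under 0.05 where 1.3 would by chance, and HES1, the Notch target HEY1, ID1, ID2 and SNAI2 passed adjusted over the list alone. The list's median F of 1.996 lay at the 99.98th percentile of 10000 matched lists, but at the 93.2nd with the arrays from 2.0 h on. The list also rose in the first 2 h and was not matched on response to serum. The rank therefore cannot tell a shared rhythm from an early response to serum. On U133B 23 were tested and 0 of the 74 genes were members, 6 having an unadjusted p under 0.05 where 1.15 would by chance. EGR1, HAS2, the Notch modifier LFNG, PHLDA1 and TNFRSF19, 5 in all, passed adjusted over the list alone, and the median F of 1.07 lay at the 77.3rd percentile, and at the 14.9th from 2.0 h on. With a correlation between neighbouring times 1 member passed on U133A (Fisher p = 0.117) and 6 on U133B (Fisher p = 0.000922).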

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

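Single arrays that stood far from the others of their window were sought in 277 groups of 4 to 6 values by Dixon's gap test. It picked out 5 groups where chance picks about 1 in 20, or 13.85 of 277, so these are values to look at and no more. All are log2 ratios.

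NR4A3, an orphan nuclear receptor, stood at 0.46 at 5.5 h on U133A, while the other arrays of 5.5 to 8.0 h lay between −0.80 and −0.36. TNFAIP3, an NF-kB inhibitor, stood at 0.43 at 0.5 h, while the other arrays up to 2.0 h lay between 1.30 and 1.46. NEFM, a neurofilament, stood at 0.84 at 7 h, while the other arrays of 5.5 to 8.0 h lay between 0.16 and 0.28. SLC25A36, a mitochondrial carrier, stood at 0.42 at 1.5 h on U133B, while the other arrays up to 2.0 h lay between −0.16 and −0.06. The mean of the circadian clock list stood at −0.12 at 12 h on U133A, while the other arrays from 9 h on lay between −0.16 and −0.15.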

How the results depend on the processing

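The spike-in covariate, the fits without the 0, 2.5 and 3.5 h arrays and the 2 scalings of the gene lists were tests chosen only after the result was seen. No paired analysis was possible because each time has 1 array of a type and the replicate numbers only name arrays in time order. Comparisons with 0 h could not be fitted without the 0 h array. A ratio carries no signal over background, so what dim probe sets limit was not measured. Where a value moved, the cause was not tested, except that some genes moved because another of their probe sets was taken.

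Over all settings, counts of calls and the HES1 amplitude kept their side of the limit in 295 cases, were stronger in 18 and weaker in 30. With median centring lower calls came to outnumber higher ones for 5.5 to 8.0 h against 0.5 to 2.0 h, on U133A (1010 higher, 1057 lower) and on U133B (419 and 442). Values of single genes kept their side of the threshold in 5911 cases, lost it in 407, gained it in 26 and changed sign in 33. List tests kept theirs in 1772, lost it in 41, gained it in 27 and changed direction in 0.

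With quantile normalization the U133A count was 26 for 0.5 to 2.0 h against 0 h, 185 for 9 to 12 h against 5.5 to 8.0 h and 1 for the 5 h rhythm, the first U133B count was 4, and TMT1A at 9 to 12 h stood at 0.0864. Slopes within windows gave 173 and 199 for these 2 U133A comparisons and 43 on U133B, the mean of the probe sets gave 124 for the later one, a first window of 0.5 to 1.5 h gave 5 on U133B and the spike-in covariate 7. With a correlation between neighbouring times, 5487 U133A and 2860 U133B genes depended on time, 53 and 450 passed for the rhythm, and 1 and 6 of these were somite clock genes. The U133A rhythm count was 69 for a period of 7 h and 83 up to 8 h. The U133B rhythm count was 12 with a linear and 35 with a cubic trend, 0 for periods of 3 h and of 4 h, 0 from 2.0 h on, and 16 without the 0, 2.5 and 3.5 h arrays, when 664 genes depended on time. With an estimated correlation 16 list tests passed, and the HES1 amplitude was 0.43, 0.52 and 0.45 for periods of 3, 6 and 7 h.

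Leaving out each array in turn gave, on U133A, 63 to 179 genes for 0.5 to 2.0 h against 0 h, 1624 to 2126 for 5.5 to 8.0 h against 0.5 to 2.0 h, 25 to 116 for 9 to 12 h, 2754 to 3453 for time dependence and 0 to 0 for the rhythm. On U133B it gave 4 to 37, 582 to 857, 776 to 1108 and, for the rhythm, 31 to 79. List tests that passed ranged from 19 to 33 and the HES1 amplitude from 0.54 to 0.71. At 9 to 12 h TMT1A ranged from −1.18 to 0.0742 and ADH1B from −1.37 to 0.0722, and on U133B SLC7A2 ranged from −0.29 to 1.68, its changed signs ending at −0.22.

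Other probe sets gave a sign against the reported one at 5.5 to 8.0 h for CALD1 (0.32, 0.36, 0.60, 0.24 and 0.04997, and 0.0733 as the mean of all), PDGFRA (0.0728), DCN (0.0223), KRT7 (0.0390), NR4A3 (0.10, and −0.11 in the first window) and SLC7A2 (−0.26), and at 9 to 12 h for ADH1B (0.0722) and TMT1A (0.0685).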

Other observations

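The tests of exchanged arrays, scaling and a brief stimulus at 0 h were chosen only after the result was seen. So were those of hybridisation and sharp early changes in the residuals around the time curves, and those of the U133B rhythm calls. The threshold of the scaling test was raised from 1 to 3 SD after its values were seen, because the genes had been picked for being high. At 1 SD scaling would have been argued against for EGR1 too.

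Circadian clock genes rose in the first 2 h on U133A, led by the repressor BHLHE40 (log2 2.64 ± 0.23), with NR1D2 at −0.74 ± 0.25, not called (adjusted p = 0.00166). Of 15, 1 was higher and 0 lower over all genes and adjusted over the list alone. By 5.5 to 8.0 h the list had fallen (adjusted p = 0.00108), with BHLHE40 (−1.60 ± 0.13), NR1D2 (−1.11 ± 0.15) and PER2 (−1.05 ± 0.22) lower and BMAL1 (0.81 ± 0.14) and CRY1 (0.67 ± 0.19, but 0.55 without 0.5 h and 0.46 without 1 h, not called) higher. Here 2 were higher and 8 lower over all genes, and 3 and 9 adjusted over the list alone. With an estimated correlation the list had an adjusted p = 0.0140 for this fall. At 9 to 12 h only BHLHE40 was called (−0.63 ± 0.13), over all genes and adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0502, under 0.05 in 12 of 27 settings).

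Genes of the unfolded protein and amino acid response fell as a group by 5.5 to 8.0 h (adjusted p = 2.99e-05, but adjusted p = 0.122 with an estimated correlation), with the transcription factors CEBPG (−1.33 ± 0.14) and CEBPB (−1.31 ± 0.19) lower and the chaperones SDF2L1 (0.73 ± 0.15) and HSPA5 (0.38 ± 0.09) higher. Of 23, 2 were higher and 11 lower over all genes, and 3 and 13 adjusted over the list alone. In the first 2 h 1 was higher and 0 lower, CHAC1 (1.69 ± 0.40, lost in 10 runs without 1 array), with 1 and 1 adjusted over the list alone (adjusted p = 0.498). At 9 to 12 h HERPUD1 was higher (0.68 ± 0.15) and ASNS (−0.73 ± 0.13) and PSAT1 (−0.64 ± 0.15) lower, each call being lost without some array, with 6 and 4 adjusted over the list alone (adjusted p = 0.967). Heat shock genes did not pass in any of the 3 comparisons, in order of time (adjusted p = 0.0705, 0.197 and 0.141, with 0.0446 for the first without 1 h). Of 12, 0, 6 and 0 were higher and 0, 2 and 1 lower over all genes, and 0, 6 and 0 higher and 0, 2 and 2 lower adjusted over the list alone. The chaperones HSPH1 (0.83 ± 0.10) and HSPE1 (0.61 ± 0.12) rose by 5.5 to 8.0 h, and HSPB8 (−0.71 ± 0.13, lost without 10 or 11 h) fell by 9 to 12 h.

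Interferon response genes were lower as a group in the first 2 h (adjusted p = 0.0307, but adjusted p = 0.399 with an estimated correlation, 0.0652 without 1.5 h, 0.121 without 2.0 h and 0.0591 with quantile normalization), with 0 of 19 called over all genes, and 0 higher and 1 lower adjusted over the list alone. They fell by 5.5 to 8.0 h (adjusted p = 0.00205, but adjusted p = 0.209 with an estimated correlation), with IFIT1 (−1.27 ± 0.17) and XAF1 (−0.86 ± 0.16) in front and OAS1 at 0.16, not called. There 0 were higher and 5 lower over all genes and adjusted over the list alone, and at 9 to 12 h 0 were called in either way (adjusted p = 0.514). Targets of p53 fell by 5.5 to 8.0 h (adjusted p = 0.00998, but adjusted p = 0.122 with an estimated correlation), with the DNA repair genes DDB2 (−0.98 ± 0.12) and XPC (−0.50 ± 0.10) and with TNFRSF10B at 0.27, not called. Of 15, 0 were higher and 5 lower over all genes and adjusted over the list alone. In the first 2 h they did not pass (adjusted p = 0.167), with 0 called over all genes and 1 lower adjusted over the list alone. At 9 to 12 h the list was lower (adjusted p = 0.0366, but adjusted p = 0.221 with an estimated correlation, 0.0510, 0.0691, 0.0518 and 0.111 without 1.5, 7, 10 and 11 h and 0.0561 with quantile normalization), with 0 called over all genes, and 0 higher and 2 lower adjusted over the list alone.

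Extracellular matrix genes did not pass as a group in the 3 comparisons (24 tested, adjusted p = 0.766, 0.498 and 0.474). LUM fell in the first 2 h, with 0 higher and 1 lower over all genes and adjusted over the list alone. TIMP3 (0.92 ± 0.12) and COL4A1 (0.54 ± 0.12) rose and FBN1 (−0.41 ± 0.10, lost in 10 runs without 1 array and with quantile normalization) fell by 5.5 to 8.0 h, with 3 higher and 2 lower in either way. At 9 to 12 h only VCAN was called (0.58 ± 0.10, but 0.35 and not called as the mean of its probe sets), in either way. Stromal surface markers did not pass either (14 tested, adjusted p = 0.498, 0.498 and 0.982). By 5.5 to 8.0 h NT5E (1.35 ± 0.15) and CD9 (0.61 ± 0.10) rose and PDGFRB (−0.69 ± 0.11) and PDGFRA (−0.52 ± 0.11, with −0.03 and 0.07 from other probe sets) fell, 4 higher and 2 lower over all genes, and 5 and 2 adjusted over the list alone. In the other 2 comparisons 0 were called over all genes, and adjusted over the list alone 1 was higher in the first, ENG (0.72 ± 0.19), and 0 in the last.

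Markers of endothelial cells (10 tested, adjusted p = 0.548, 0.541 and 0.803 in order of time) and of blood cells (10 tested, adjusted p = 0.672, 0.967 and 0.498) had 0 called in any comparison, over all genes and adjusted over the list alone. Epithelial markers (8 tested, adjusted p = 0.541, 0.767 and 0.498) had KRT18 higher (0.69 ± 0.13) and KRT7 lower (−0.26 ± 0.09, with 0.04 from another probe set) by 5.5 to 8.0 h, and 0, 2 and 1 higher and 0, 1 and 0 lower adjusted over the list alone. Adipocyte, muscle and bone markers (14 tested, adjusted p = 0.0738, 0.906 and 0.817, with 0.0400 for the first without 1 h) had SOX9 higher (0.96 ± 0.16) and PPARG lower (−0.43 ± 0.12, lost without 1 h) by 5.5 to 8.0 h and 0 others called over all genes, and 1, 1 and 0 higher and 1, 1 and 0 lower adjusted over the list alone. In 7 list tests, none past the threshold, the median, the mean and the test differed in sign. They were ribosome biogenesis in the first 2 h (median −0.02, mean 0.04, test up) and blood cell markers there (−0.01, 0.01, up) and by 5.5 to 8.0 h (0.04, 0.01, down), MAPK feedback inhibitors (0.04, −0.14, down) and adipocyte, muscle and bone markers (−0.00, 0.04, down) by 5.5 to 8.0 h, and quiescence and FOXO targets (−0.08, 0.01, down) and stromal markers (−0.00, 0.01, up) at 9 to 12 h.

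FOS had a ratio of 33.4 at 0 h and 32.7 at 0.5 h, and JUN (2.94), EGR1 (2.37), ATF3 (2.29) and FOSB (2.25) were also high at 0 h, before serum. An exchange of the 0 and 0.5 h arrays is argued against, since 0.5 h resembled 1 h more closely than 0 h did on U133A, by 0.288 in correlation across genes (0.614 against 0.327, bootstrap SD over genes 0.0211), and by 0.0591 (SD 0.0174) on U133B. Scaling of the 0 h array as the whole cause is argued against for FOS, which lay 4.51 on the log2 scale above the array's spike-in ratio (SD over arrays 0.32), and narrowly for JUN (1.00 above), but stays open for EGR1 (0.69 above). A brief stimulus of the starved cells before harvest may have raised them, with 11 of 31 immediate early genes above their later range by over 1 SD at 0 h, though not NR4A1, NR4A2, NR4A3, EGR3 or SGK1. FOS, JUN and EGR1, picked for being high, are among the 11. The share of all genes above their later range in this way was not computed. The 0 h array had the widest spread over genes on U133A (SD 0.350), which can place more genes there. A brief stimulus cannot be told apart from a high starved level, because 0 h is a single harvest.

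Residuals of neighbouring arrays around the smooth time curves had autocorrelations of −0.39 on U133A and −0.36 on U133B, and 1 component held 29.2% and 32.3% of the residual variance. Fitting a curve by itself makes neighbouring residuals negatively correlated, by an amount that was not computed. The autocorrelations therefore do not show that neighbouring arrays swung against each other. Hybridisation or scanning noise of each array alone, as the cause of this component, is argued against. The component's scores correlated between the 2 types (17 times, Pearson r = 0.822, permutation p = 9e-05, Spearman 0.748, p = 0.00077, r = 0.762 without the 2 farthest times, adjusted p = 0.00045 and 0.00192 over 5 relations). Hybridisation effects shared by the 2 arrays of a time stay open, since spike-in ratios were also alike between types (r = 0.687). The permutations take the times as exchangeable, which residuals of a fitted curve are not, so their p-values may be too small. Sharp early changes are argued against by r = 0.890 from 3 h on (11 times, permutation p = 0.00021, Spearman 0.918, p = 0.00017, 0.826 without the 2 farthest, adjusted p = 0.000525 and 0.00085). The amount of labelled target cannot be told apart, with r = −0.311 to the spike-in ratio on U133A (21 arrays, permutation p = 0.171, Spearman −0.343, p = 0.128, −0.277 without the 2 farthest, adjusted p = 0.194 and 0.132) and −0.330 on U133B (p = 0.194, Spearman −0.380, p = 0.132, but −0.594 without the 2 farthest), because spike-in ratios were themselves alike between types (r = 0.687, permutation p = 0.00203, Spearman 0.667, p = 0.00437). Differences between flasks could give the same pattern and were not tested, and no biological explanation was tested.

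The genes that passed the 5 h test on U133B may reflect 1 pulse after serum. Among 70 of them with a first peak within 3 h, the second rise was a median of 0.159 of the first (quartiles −0.107 and 0.318), and it was above 0 in 46. For the genes as a set the log2 ratios thus did not return to a similar height after 5 h, which a single pulse needs. The rises were taken without removing the trend that the 5 h test fits, for genes called on these same values. A slow fall over time lowers the second rise and raises the first. A 5 h wave on such a trend therefore stays open. In 7 genes, named after their values were seen, the second rise was at least as large as the first: BDNF (2.53 of the first), SMURF2 (1.98), ATOH8 (1.59), PRAG1 (1.48), UGCG (1.205), CDC42EP3 (1.05) and DLC1 (1.02). A strongly damped wave was not tested and stays open.

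Random splits of the same arrays gave fewer genes than the real one in 3 comparisons, with 1 of 100 splits, the real one, giving as many genes in each, so a random grouping of the arrays can be excluded. The arrays are consecutive times, so any smooth drift over time, biological or technical, gives the real split the most genes, and the splits do not exclude it. On U133A 2048 genes passed for 5.5 to 8.0 h against 0.5 to 2.0 h and at most 409 in another split, and for 9 to 12 h against 5.5 to 8.0 h the numbers were 73 and 32, although 25, 26, 39 and 44 genes passed without 12, 11, 10 or 6.5 h. On U133B they were 804 and 310 for 5.5 to 8.0 h against 0.5 to 2.0 h.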
